A study of Homo sapiens with 6 samples.

How the data were processed

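RNA abundance was measured on 6 Human Genome U133 oligonucleotide arrays, 3 from HL-60 derivatives that stably expressed an shRNA against USP2 and 3 from derivatives with a control shRNA. HL-60 is an established human promyelocytic leukaemia line. PMA, a phorbol ester, drives it toward a macrophage-like state, and lipopolysaccharide (LPS) is the bacterial ligand of Toll-like receptor signalling. Per the labels, all 6 samples received PMA at 30 nM for 3 days and then LPS at 10 µg/mL for 4 h. Groups and replicate numbers were taken from the sample titles. The labels do not say that the replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical.

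The deposited values were linear probe set intensity, 1 signal per probe set and array, with no logarithm taken. Per the submitters' processing notes they came from GCOS, the Affymetrix operating software, whose version and settings are not given in the sources used here. The mean signal of each array between its 2nd and 98th percentiles was 499.91 or 499.92, a common scaling of all 6 arrays. Detection calls were not used here. The medians of the log2 signals ran from 6.35 to 6.46 over the 6 arrays, so no further array normalization was added. Array intensities have no counting depth, and the number of arrays limits the precision.

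The table held 54675 probe sets. Gene symbols came from the platform annotation: 41091 probe sets had exactly 1 symbol, 1801 had several, 11721 had none and 62 were control probe sets. Of those with 1 symbol, 41037 matched an Entrez identifier in the RefSeq gene table, and 0 symbols needed an update. No gene was named from a probe set with several symbols or none. A probe set with 1 symbol may still detect near-identical copies of its gene, so the signals of such genes, CCL4 and HCAR3 among them, are uncertain. Some genes of the fixed lists and some genes fixed for naming are not reported here. No genome was used, so no coordinates are given.

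Signals below 7.34, the 10th percentile of all values, were raised to that floor and converted to log2. Control probe sets were left out of the fit. Probe sets were tested where their mean log2 value over the 6 arrays reached the median of all probe sets other than controls (6.13, a signal of 70.1), which left 27307 probe sets. Differences, USP2 shRNA minus control shRNA, were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), and p-values were adjusted by the Benjamini-Hochberg method over all probe sets tested, with a threshold of 0.05. A fold is 2 raised to the fitted log2 difference. For each of 11801 genes, the probe set with the highest mean stood for the gene. Where another tested probe set of a named gene had the opposite sign, the text gives its value.

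Shifts of 23 gene lists were tested with camera from limma, with a preset correlation of 0.01 between genes, against all other tested genes and adjusted over the 23 lists. Camera with a correlation estimated from the data and fry were run beside it. The lists covered inflammatory cytokines; chemokines; NF-kB feedback and target genes; interferon-stimulated genes; the Toll-like receptor pathway; monocyte and macrophage markers; promyelocyte and granulocyte markers; lymphoid markers; erythroid and megakaryocyte markers; epithelial and fibroblast markers; lipid handling and metabolic inflammation; fatty acid and sterol synthesis; cell cycle; p53 target genes; the circadian clock; antigen presentation; hypoxia and glycolysis; unfolded protein and integrated stress response; heat shock and oxidative stress; matrix, adhesion and proteolysis; ubiquitin-specific proteases; ribosomal proteins; and oxidative phosphorylation. The cytokine, chemokine and lipid lists were drawn up with knowledge of published work on USP2 in myeloid cells.

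The groups, the tests, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule named USP2, the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold whose groups did not overlap, up to 4 members of each list with the smallest p, and a short set of genes fixed by name. The alternatives were quantile normalization, median centring, other floors or a pseudocount of 16, other filters, other variance models, array weights, the replicate number as a block, other ways of combining probe sets, leaving out each array in turn, and the other list tests. A covariate for labelling, a looser threshold of 0.1 and camera with an estimated correlation under each alternative that gave a list a new call were added after the data were seen. Values of controls were compared between groups with exact two-sided permutation tests, for which 3 against 3 arrays allow no p below 0.1.

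The fit was tested on simulated data for USP2 shRNA against control shRNA, with 200 of 27307 probe sets changed. Of the 50 probe sets changed by each fold, it recovered 16% at 1.5-fold, 36% at 2-fold, 72% at 4-fold and 80% at 8-fold, and 0 unchanged probe sets passed. The probe sets standing for the hypoxia and glycolysis list were also shifted and are not counted among the unchanged. Noise was drawn independently for each probe set, with no correlation between genes and no deviating array. These rates therefore need not hold for the real arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.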

Results

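Transcript levels of HL-60 derivatives carrying an shRNA against USP2, a ubiquitin-specific protease, were compared with those of derivatives carrying a control shRNA, with 3 arrays per group. All cells had been treated with PMA and then with LPS, and the comparison asked how their expression profiles differed. An effect of silencing USP2 cannot be told apart here from an off-target effect of the shRNA or another difference between the derivatives. No arm without LPS was analysed here, so the values describe stimulated cells and not their response to LPS. Pairwise correlations of the log2 values between arrays ran from 0.9505 to 0.9683.

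The targeted transcript was lower on every USP2 shRNA array. The USP2 signal was 451.3 ± 94.6 with USP2 shRNA and 1511 ± 188 with control shRNA (SD, n = 3 each), 3.38-fold lower, with a log2 difference of -1.76 ± 0.17 (SE; limma adjusted p = 0.0074). The USP2 shRNA arrays gave 548, 447 and 359, and the control arrays gave 1301, 1664 and 1567. Another USP2 probe set fell 2-fold, with a log2 difference of -1.0 ± 0.13 (SE; limma adjusted p = 0.021). A dimmer USP2 probe set had a log2 difference of -0.63 ± 0.43 (SE; limma adjusted p = 0.63), and 1 more lay below the filter. The exact permutation p was 0.1 for each of the 3 tested USP2 probe sets, the smallest that 3 against 3 arrays allow. The limma call on USP2 ended without control shRNA replicate 2 (adjusted p = 0.107), without control shRNA replicate 3 (adjusted p = 0.0519), with no filter (adjusted p = 0.086) and with no intensity trend (adjusted p = 0.387), while its adjusted p ran from 0.0027 to 0.39 over its 20 alternatives.

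Outside the target, 9 genes rose and 3 fell in the USP2 shRNA cells. FABP4, a fatty acid-binding protein of adipocytes and macrophages, rose 4.67-fold, from a signal of 970.8 ± 263.6 to 4492 ± 874 (SD, n = 3 each; log2 difference 2.22 ± 0.19 SE, limma adjusted p = 0.0032). SERPINE2, a serine protease inhibitor, rose 3.37-fold, from 1575 ± 227 to 5310 ± 777 (SD, n = 3 each; log2 difference 1.75 ± 0.13 SE, limma adjusted p = 0.0016). The cytokine TNF rose 1.54-fold from an already high signal, 9846 ± 336 to 15171 ± 1346 (SD, n = 3 each; log2 difference 0.62 ± 0.081 SE, limma adjusted p = 0.026). TYMS, the thymidylate synthase of DNA synthesis, was 1.75-fold lower, at 2362 ± 91.0 against 4134 ± 153 (SD, n = 3 each; log2 difference -0.81 ± 0.083 SE, limma adjusted p = 0.008).

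The other genes that rose were CD300A, an inhibitory receptor of myeloid cells, at 3.39-fold, the transcription factor ETS1 at 2.81-fold, the adaptor SLA at 1.93-fold, the protease inhibitor TFPI2 at 1.77-fold, the monoacylglycerol lipase MGLL at 1.76-fold and GCH1, which starts tetrahydrobiopterin synthesis, at 1.66-fold. Their SEs ran from 0.088 for GCH1 to 0.23 for CD300A on the log2 scale. The PCNA-binding protein PCLAF fell 1.69-fold and MS4A7, a membrane protein of macrophages, fell 1.85-fold. For each of these 13 genes, USP2 included, the 3 USP2 shRNA arrays lay on one side of the 3 control arrays. The second TFPI2 probe set rose by about as much (log2 difference 0.83, adjusted p = 0.008). Other probe sets of SLA, MGLL, PCLAF, TYMS and MS4A7 had the same sign without passing, and 1 of the MS4A7 probe sets lay at -0.04.

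**Figure D1:**
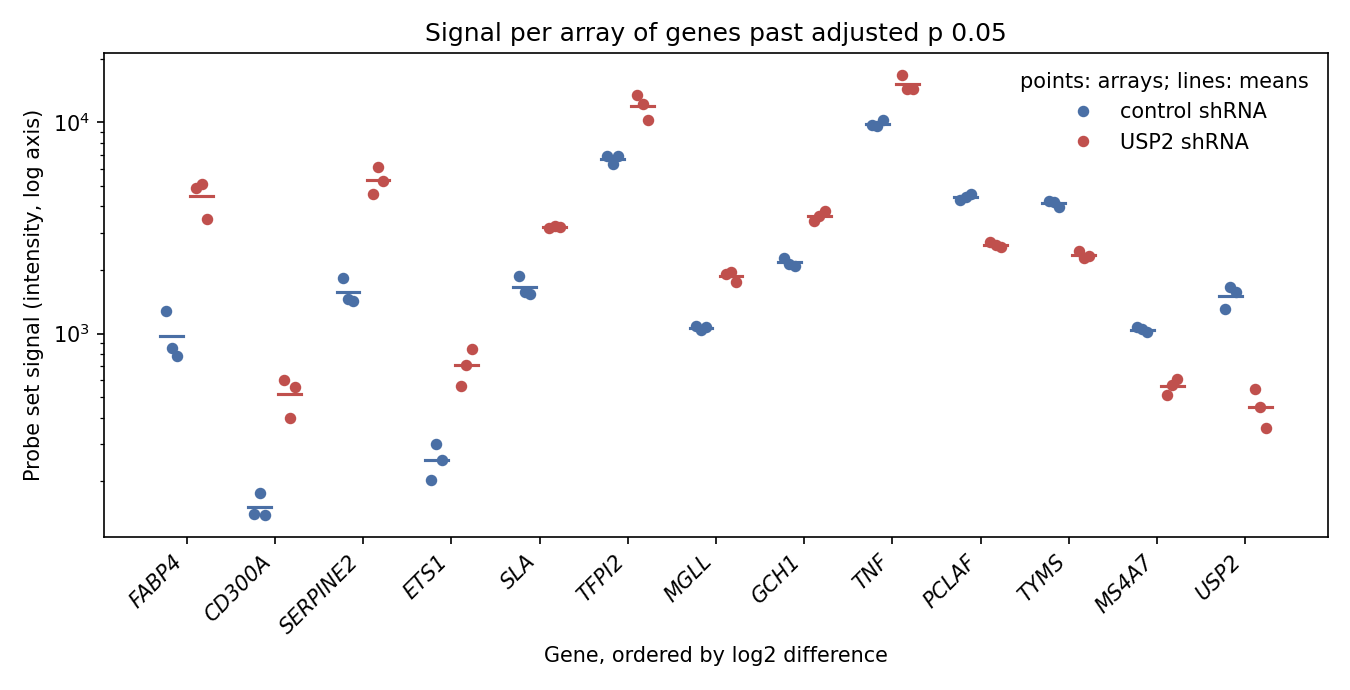
Probe set signal (intensity, log axis) on each of the 6 arrays for the 13 genes past adjusted p 0.05, ordered by log2 difference, with control shRNA in blue, USP2 shRNA in red, points for arrays and lines for group means. The groups overlap for none of the 13 genes, from FABP4 at a log2 difference of 2.22 to USP2 at -1.76.

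Among 27307 probe sets tested with limma, 11 were higher and 6 lower past an adjusted p of 0.05, which gave 9 genes higher and 4 lower out of 11801. Of these, 4 genes rose and 1 fell by at least 2-fold. At an unadjusted p below 0.05, 1389 probe sets were higher and 1544 lower, against 2053 and 1102 with median centring and 1538 and 1411 with quantile normalization. The groups did not overlap for 17.1% of the tested probe sets, against 10% by chance, and the median log2 difference of all of them was -0.01. A further 30 probe sets lay at an adjusted p from 0.05 to 0.055, and 48 genes were higher and 30 lower at the looser threshold of 0.1, which was chosen after seeing the data. Median centring gave 32 genes higher and 7 lower, while limma with no filter or with no intensity trend gave 0 genes, with 4330 and 2513 probe sets at an unadjusted p below 0.05. Leaving out USP2 shRNA replicate 1, 2 or 3 gave 5, 2 or 40 genes higher and 4, 1 or 24 lower, and leaving out control shRNA replicate 1, 2 or 3 gave 3, 2 or 2 higher and 1, 0 or 0 lower. The pair of zero counts stood beside 996 and 1449 probe sets lower at an unadjusted p below 0.05. FABP4 and SERPINE2 passed without each of the 6 arrays in turn, while CD300A, ETS1, TFPI2, MGLL, TNF and MS4A7 passed only where the array left out was USP2 shRNA replicate 3. GCH1, TYMS and PCLAF did not pass without USP2 shRNA replicate 2 or without any 1 control array, and SLA did not pass without USP2 shRNA replicate 2 or control shRNA replicate 2 or 3. With the mean of all probe sets of a gene, TYMS (log2 difference -0.535, adjusted p = 0.116) and MS4A7 (-0.49, adjusted p = 0.234) did not pass. Fitted with the replicate number as a block, CD300A (limma adjusted p = 0.0543), TNF (limma adjusted p = 0.0581) and MS4A7 (limma adjusted p = 0.0622) did not pass either.

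Cytokine transcripts were higher as a group. Of 18 inflammatory cytokines tested, 14 were higher with USP2 shRNA, and the median log2 difference was 0.25 (camera adjusted p = 0.0029; adjusted p = 0.32 with an estimated correlation). Adjusted over the list alone, 6 rose and 1 fell, against 1 that rose over all genes, TNF. LIF, a cytokine of the interleukin 6 family, had a 1.99-fold higher signal, 1124 ± 174 against 562.3 ± 52.5 (SD, n = 3 each; log2 difference 0.99 ± 0.15 SE, limma adjusted p = 0.0501 over all genes). INHBA, the activin A subunit, had a log2 difference of 0.37 ± 0.088 (SE) in the probe set that stands for it, while its other probe sets lay at 0.15 and -0.08. IL18 fell by 0.29 on the log2 scale, adjusted over the list alone. IL1B was among the brightest probe sets on the arrays, at 68011 ± 9719 against 58310 ± 4022 (SD, n = 3 each; log2 difference 0.21 ± 0.10 SE, limma adjusted p = 0.5). IL6 was dim in both groups, at 105.6 ± 3.99 and 95.98 ± 6.30 (SD, n = 3 each; limma adjusted p = 0.92). The list's call ended with the mean of all probe sets of a gene (median 0.143, adjusted p = 0.0651), without _x_at and _s_at probe sets (median 0.214, adjusted p = 0.277) and by fry (adjusted p = 0.0683). It was drawn up with knowledge of published USP2 work, so its direction is not independent evidence.

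Chemokine transcripts were also higher as a group, with 12 of 14 tested members above the controls and a median 1.30-fold difference (log2 0.37; camera adjusted p = 6.11e-05; adjusted p = 0.11 with an estimated correlation). Adjusted over the list alone 6 rose, and over all genes 0 did. The 6 were CCL1, CCL2, CCL4, CCL7, CCL20 and CXCL2. CCL4, which attracts monocytes and T cells, reached 44386 ± 5619 against 32852 ± 2977 (SD, n = 3 each; log2 difference 0.43 ± 0.10 SE, limma adjusted p = 0.18 over all genes). CCL20 reached 45652 ± 4790 against 34717 ± 2708 (SD, n = 3 each; limma adjusted p = 0.17 over all genes). CCL2, the monocyte chemoattractant, had a log2 difference of 1.62 ± 0.48 (SE; limma adjusted p = 0.27 over all genes), with USP2 shRNA signals of 317, 132.9 and 653 against 106, 98.3 and 90.7. CCL7 had a log2 difference of 1.15 ± 0.30 (SE; limma adjusted p = 0.21 over all genes). CXCL8, also among the brightest probe sets, had a log2 difference of 0.23 ± 0.11 (SE; limma adjusted p = 0.51). The caution about how the cytokine list was drawn up applies to this list too. By limma 6 of the 14 had an unadjusted p below 0.05, and fry also gave the list a call (adjusted p = 0.02).

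NF-kB feedback and target genes had a small shift, with 23 of 30 members higher and a median log2 difference of 0.08 (camera adjusted p = 0.00666; adjusted p = 0.32 with an estimated correlation). Adjusted over the list alone 4 rose, TNIP1, TNFAIP6, REL and PTGS2, and over all genes 0 did, with 7 at an unadjusted p below 0.05 by limma. PTGS2, the inducible cyclooxygenase, had a log2 difference of 0.42 ± 0.12 (SE; limma adjusted p = 0.25 over all genes), and TNIP1, an inhibitor of NF-kB signalling, had 0.31 ± 0.07 (SE; limma adjusted p = 0.15 over all genes). Another TNIP1 probe set lay at -0.34, and the other REL probe sets ran from -1.18 to 0.27. This list's call ended without USP2 shRNA replicate 1 (adjusted p = 0.146), without control shRNA replicate 3 (adjusted p = 0.0531), with the mean of all probe sets of a gene (adjusted p = 0.0917), without _x_at and _s_at probe sets (adjusted p = 0.243) and by fry (adjusted p = 0.0778). Its median ran from 0.055 to 0.157 over the alternatives. The median log2 difference of 24 Toll-like receptor pathway genes was 0.00, with 12 higher and 12 lower (camera adjusted p = 0.778). That of 29 interferon-stimulated genes was also 0.00, with a mean of -0.04 (camera adjusted p = 0.778). In both lists 0 genes passed adjusted over the list alone or over all genes by limma, and 3 in each had an unadjusted p below 0.05, led by GBP2 at 0.0048, whose other probe set lay at -0.08 on the log2 scale, and IRAK1 at 0.0069.

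**Figure D2:**
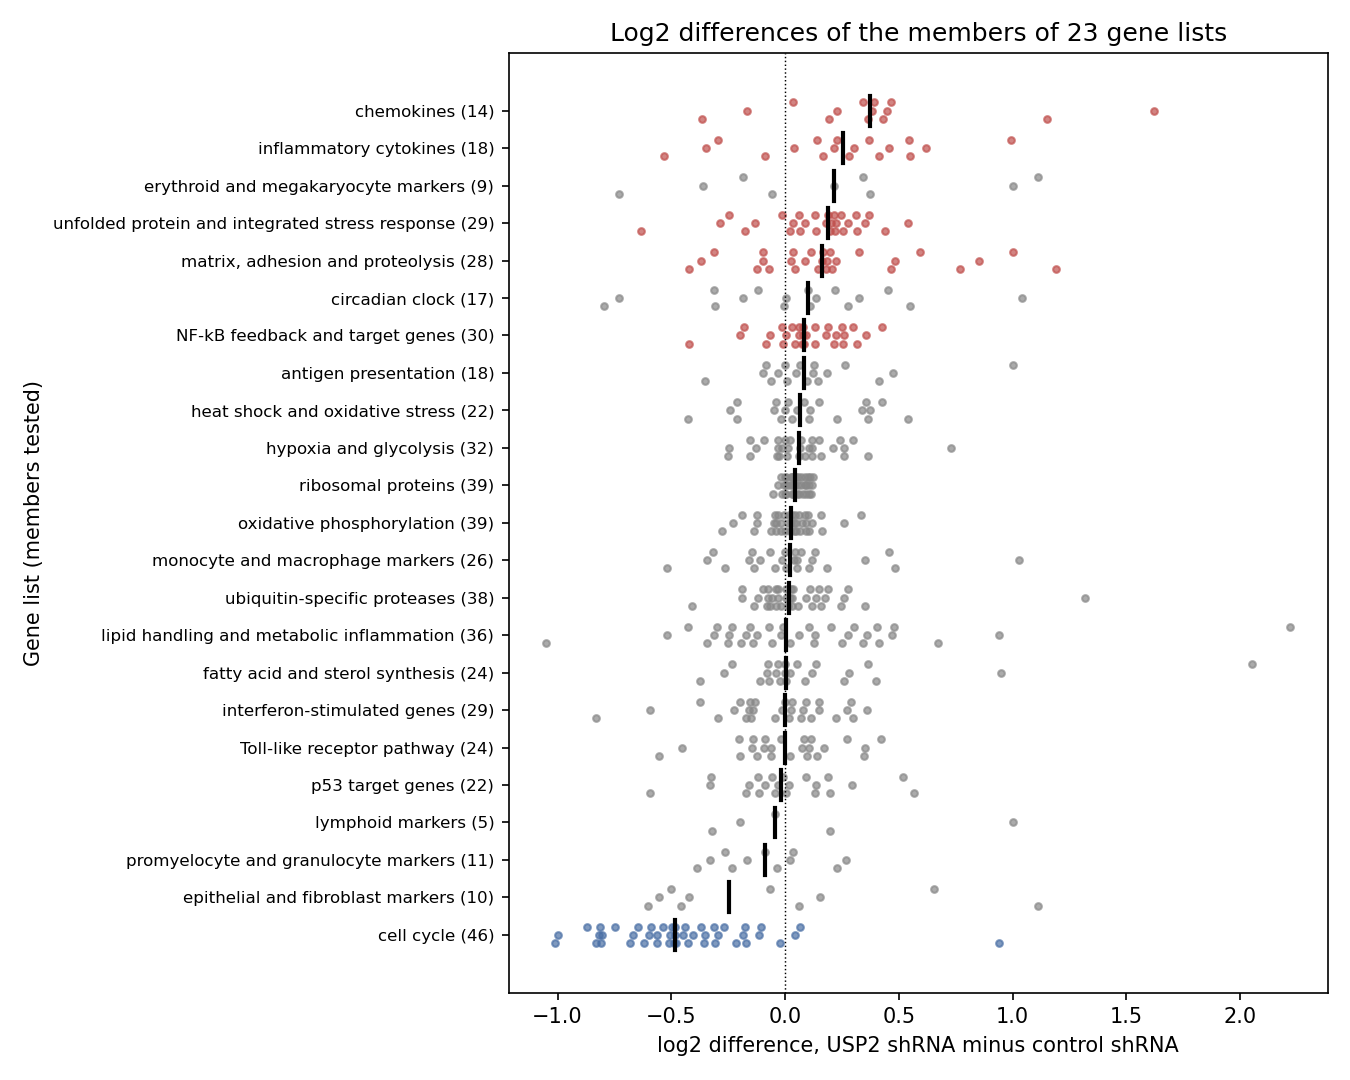
Log2 difference, USP2 shRNA minus control shRNA, of each tested member (points) of the 23 gene lists, with the number tested in brackets and the median as a black bar, in red for lists higher by camera, blue for lower and grey for the rest. Chemokines have the highest median at 0.37 and cell cycle genes the lowest at -0.48.

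Cell cycle transcripts formed the list with the largest shift. Of 46 members tested, 43 were lower with USP2 shRNA, with a median 1.40-fold fall (log2 -0.48; camera adjusted p = 2.04e-20; adjusted p = 0.08 with an estimated correlation). Adjusted over the list alone 19 fell, against 1 over all genes, TYMS. TOP2A, the topoisomerase of dividing cells, was at 600.5 ± 97.7 against 1203 ± 176 (SD, n = 3 each; log2 difference -1.01 ± 0.16 SE, limma adjusted p = 0.0502 over all genes). UBE2C and CCNB2, which act in mitosis, had log2 differences of -0.87 ± 0.14 and -0.81 ± 0.13 (SE; limma adjusted p = 0.051 for each over all genes). CCND1, cyclin D1, did not pass, and its probe sets disagreed: 1 had a log2 difference of -0.51 ± 0.24 (SE), with USP2 shRNA signals of 6382, 6901 and 3134, and the other -0.05 ± 0.079 (SE). Fry also gave the cell cycle list a call (adjusted p = 0.007). The 28S ribosomal RNA 5′ control signal was lower on the same arrays, at 14005 ± 965 against 26123 ± 3706 (SD, n = 3 each; exact permutation p = 0.1). Among the ribosomal controls it had the largest difference, and a link to the cell cycle list was not tested.

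**Figure D3:**
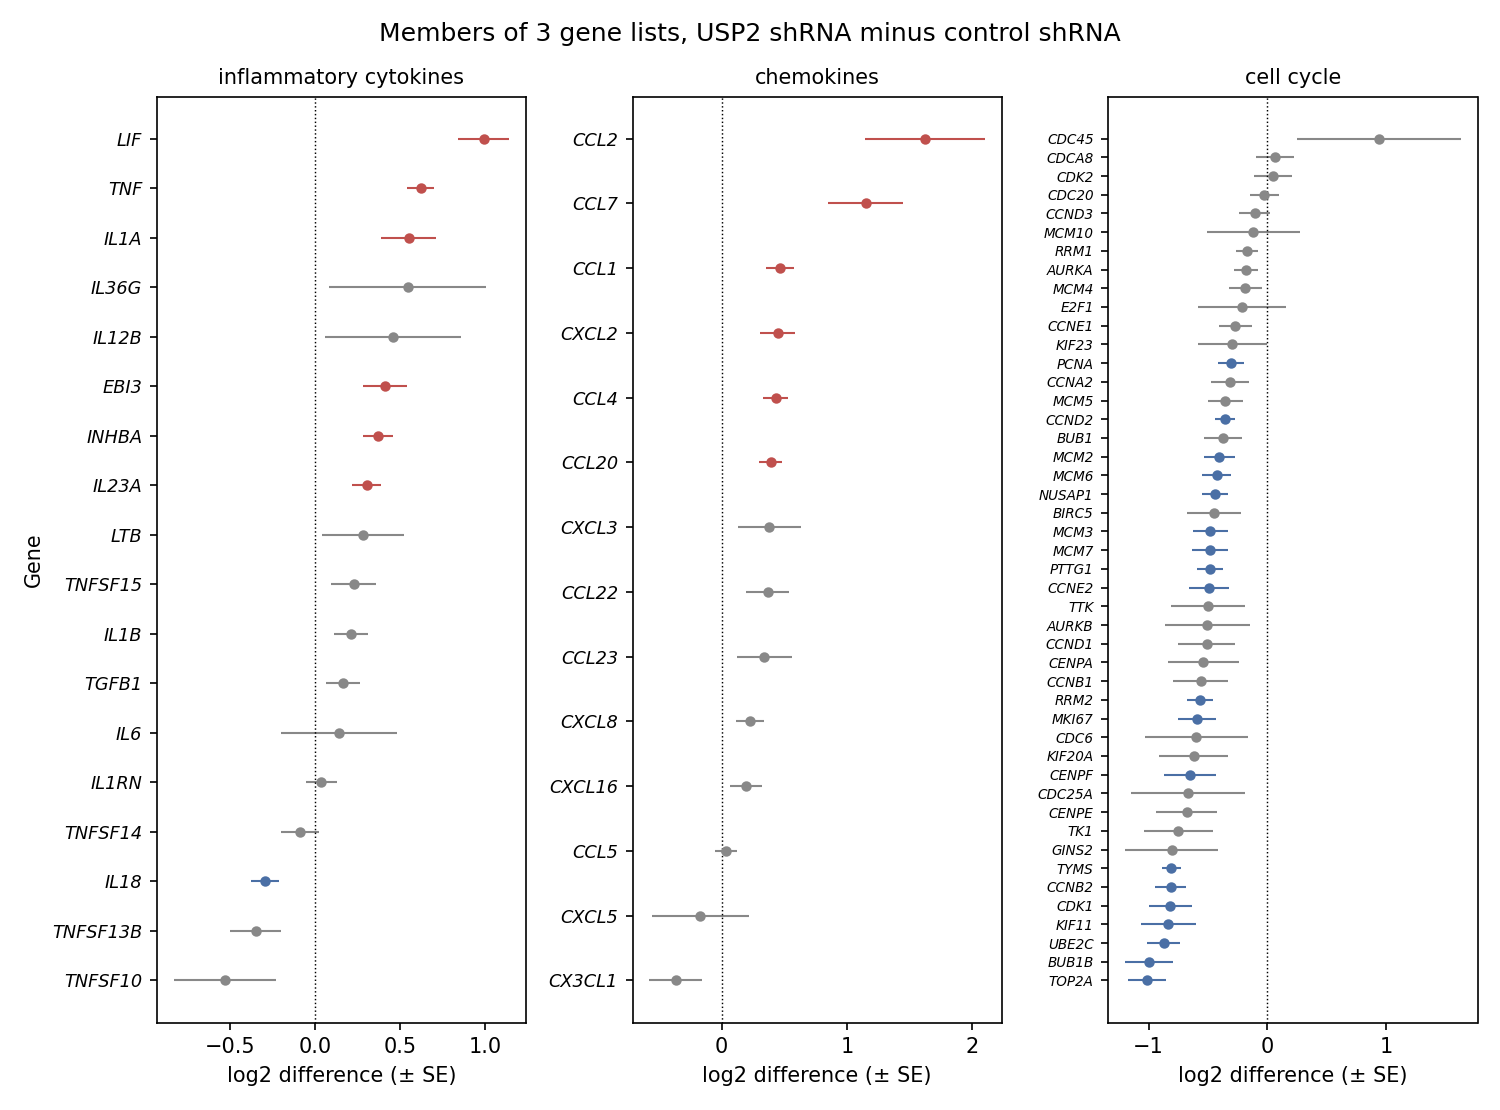
Log2 difference ± SE, USP2 shRNA minus control shRNA, of each tested member of the inflammatory cytokine, chemokine and cell cycle lists, with red for genes that rose and blue for genes that fell adjusted over the list alone and grey for the rest. Of the cell cycle genes 43 of 46 lie below 0, and of the chemokines 12 of 14 lie above it.

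Lipid handling genes moved in both directions. Of 36 tested, 11 rose and 5 fell adjusted over the list alone, and over all genes only FABP4 passed. The median log2 difference was 0.01 (camera adjusted p = 0.583). LIPA, the lysosomal acid lipase, reached 6385 ± 165 against 4025 ± 505 (SD, n = 3 each; log2 difference 0.67 ± 0.099 SE, limma adjusted p = 0.0501 over all genes). NPC2, which carries cholesterol out of lysosomes, had a log2 difference of 0.40 ± 0.077 (SE; limma adjusted p = 0.082 over all genes). ABCG1, a cholesterol exporter, had one of -1.05 ± 0.20 (SE; limma adjusted p = 0.085 over all genes), and its dim other probe sets lay at -0.87 and 0.36. The list held FABP4 by prior knowledge of USP2 work, so its direction is not independent evidence. Among 24 genes of fatty acid and sterol synthesis, STARD4 and ELOVL6 rose and SCD fell adjusted over the list alone, and 0 passed over all genes, with 6 at an unadjusted p below 0.05 by limma (median log2 difference 0.00; camera adjusted p = 0.778). SCD, the stearoyl-CoA desaturase, was at 15728 ± 1555 against 20322 ± 1369 (SD, n = 3 each), and FASN, the fatty acid synthase, at 467.4 ± 115.5 against 460.3 ± 67.0 (SD, n = 3 each).

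Genes of matrix, adhesion and proteolysis were higher as a group, with 21 of 28 above the controls and a median log2 difference of 0.16 (camera adjusted p = 0.0017; adjusted p = 0.17 with an estimated correlation). Adjusted over the list alone 5 rose, MMP7, ADAMDEC1, FN1, ITGA6 and TIMP1, and TIMP2 fell, while 0 passed over all genes and 11 had an unadjusted p below 0.05 by limma. The metalloproteinase MMP7 reached 21336 ± 2550 against 14083 ± 784 (SD, n = 3 each; log2 difference 0.59 ± 0.095 SE, limma adjusted p = 0.0502 over all genes). FN1, fibronectin, had a log2 difference of 1.19 ± 0.22 (SE; limma adjusted p = 0.075 over all genes), and its other 3 probe sets lay from 0.86 to 1.5. Another ITGA6 probe set lay at -0.01. Fry gave this list an adjusted p of 0.042. Its median was 0.096 without USP2 shRNA replicate 1 (camera adjusted p = 0.0203) and 0.089 without _x_at and _s_at probe sets (camera adjusted p = 0.00861).

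Genes of the unfolded protein and integrated stress response were higher in 23 of 29 cases, with a median log2 difference of 0.19 (camera adjusted p = 0.00152; adjusted p = 0.32 with an estimated correlation). By limma 0 members passed adjusted over the list alone or over all genes, and 11 had an unadjusted p below 0.05, led by SLC7A11 at 0.0018, with a log2 difference of 0.54 in that probe set and -0.38 in a dim one. ATF4, a transcription factor of the integrated stress response, had a log2 difference of 0.28 ± 0.085 (SE; limma adjusted p = 0.29), and the chaperone HSP90B1 had -0.63 ± 0.18 (SE; limma adjusted p = 0.25), with 0.27 for its other probe set. The call on this list ended without USP2 shRNA replicate 1 (adjusted p = 0.0654) and by fry (adjusted p = 0.0683), and its median was 0.098 without _x_at and _s_at probe sets. Heat shock and oxidative stress genes did not pass as a list (camera adjusted p = 0.225; median log2 difference 0.07). Adjusted over that list alone 6 rose and 1 fell, with BAG3 at 0.43 ± 0.087 (SE) and TXNRD1 at 0.38 ± 0.087 (SE) on the log2 scale, and 0 passed over all genes, with 9 at an unadjusted p below 0.05 by limma.

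Lists of cell identity markers did not pass. Among 26 monocyte and macrophage markers CD86 rose and CD36 and MSR1 fell adjusted over the list alone, 0 passed over all genes with 4 at an unadjusted p below 0.05 by limma, and the median log2 difference was 0.02 (camera adjusted p = 0.778, with the opposite sign). CD86, a costimulatory receptor, reached 7309 ± 970 against 5299 ± 348 (SD, n = 3 each), and the scavenger receptor CD36 was at 6752 ± 212 against 8556 ± 420 (SD, n = 3 each). The LPS co-receptor CD14 was dim, at 152.9 ± 18.6 against 125.0 ± 48.6 (SD, n = 3 each; limma adjusted p = 0.75). Of 11 promyelocyte and granulocyte markers 7 were lower, with a median log2 difference of -0.09 (camera adjusted p = 0.583), and MPO, myeloperoxidase, was at 1234 ± 146 against 1314 ± 166 (SD, n = 3 each). Markers of other lineages did not pass either. The 5 lymphoid markers had a median of -0.05 with a mean of 0.13 (camera adjusted p = 0.961). The 9 erythroid and megakaryocyte markers had 0.21 (camera adjusted p = 0.583), and the 10 epithelial and fibroblast markers -0.24 (camera adjusted p = 0.583). In these 4 lists limma passed 0 genes adjusted over the list alone or over all genes, and 2, 1, 1 and 1 had an unadjusted p below 0.05, led by SRGN at 0.005, with a log2 difference of 0.23 in that probe set and -0.03 in a dim one.

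Of 17 circadian clock genes BMAL1, a core clock transcription factor, rose adjusted over the list alone, at 684.0 ± 86.8 against 334.5 ± 55.9 (SD, n = 3 each; log2 difference 1.04 ± 0.18 SE, limma adjusted p = 0.065 over all genes). By limma 6 of the 17 had an unadjusted p below 0.05, 3 higher and 3 lower, among them CRY2 at -0.73 ± 0.26 and DBP at -0.80 ± 0.31 (SE; limma adjusted p = 0.35 and 0.39 over all genes), and 0 passed over all genes. The list as a whole had a median of 0.10 (camera adjusted p = 0.778), with 10 higher and 7 lower. Camera looks for a shared direction, so it can miss a list whose members move both ways. Fry's mixed test, for change in either direction, gave an unadjusted p of 5.1e-08, the smallest of the 23 lists. For the unfolded protein and integrated stress response list it gave 2.3e-07. No call was made from the mixed test. Among 22 p53 target genes PLK3 and GADD45A rose adjusted over the list alone, 0 passed over all genes with 4 at an unadjusted p below 0.05 by limma, and the median was -0.02 with a mean of 0.00 (camera adjusted p = 0.778). CDKN1A had a log2 difference of 0.29 ± 0.093 (SE; limma adjusted p = 0.3) and MDM2, the ligase of p53, -0.03 ± 0.13 (SE; limma adjusted p = 0.96), with other probe sets from -0.29 to 0.39. A dim PLK3 probe set lay at -0.40. The remaining lists did not pass by camera in the reported fit and had 0 genes past limma's threshold adjusted over the list alone or over all genes. They were antigen presentation (18 genes, median log2 difference 0.08, adjusted p = 0.425), hypoxia and glycolysis (32 genes, 0.06, adjusted p = 0.583), ubiquitin-specific proteases other than USP2 (38 genes, 0.02, adjusted p = 0.778), ribosomal proteins (39 genes, 0.05, adjusted p = 0.34) and oxidative phosphorylation (39 genes, 0.03, adjusted p = 0.782). At an unadjusted p below 0.05 they had 3, 2, 2, 0 and 5 genes, in that order, led by ATP5MC1 at 0.0061 and HLA-DMA at 0.0088. Ribosomal proteins passed, with higher medians, without USP2 shRNA replicate 3 (0.128, camera adjusted p = 1.26e-07), without control shRNA replicate 3 (0.082, adjusted p = 0.025), with median centring (0.095, adjusted p = 0.00444), with array weights (0.092, adjusted p = 0.00196) and with the labelling covariate (0.164, adjusted p = 1.55e-08), while their median was -0.01 with quantile normalization. None of these 5 calls held with an estimated correlation, which was 0.58 to 0.75 (adjusted p = 0.70 to 0.86 with an estimated correlation under the same 5 settings, and 0.83 in the reported fit). Antigen presentation passed without USP2 shRNA replicate 3 (0.153, camera adjusted p = 0.00976) and with the labelling covariate (0.174, adjusted p = 0.00418). Neither call held with an estimated correlation (adjusted p = 0.33 and 0.37 with an estimated correlation under the same settings, and 0.80 in the reported fit).

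By camera with the preset correlation, 5 of the 23 lists were higher and 1 lower. With an estimated correlation 0 passed, and by fry for a shared direction 3 did, chemokines, cell cycle and matrix genes. Camera with the preset correlation gave 6 lists in 3 of the 10 splits of the arrays into 3 and 3, the real one included. The number of lists called therefore does not set the real grouping apart. Each other split mixes both groups unevenly, so part of the real difference stays in it. Its count does not show how many lists pass with no difference.

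Control probe sets differed between the groups in part. The 28S ribosomal RNA 5′ signal was 1.86-fold lower with USP2 shRNA (log2 difference -0.89), and the 18S 3′ signal was 1.67-fold lower, at 2520 ± 295 against 4253 ± 941 (SD, n = 3 each; exact permutation p = 0.1). The 28S middle signal was 1.21-fold lower (exact permutation p = 0.1), the 18S 5′ signal 1.30-fold lower and the 18S middle signal 1.23-fold lower (exact permutation p = 0.2 for each). The 3′ to 5′ ratio of GAPDH was 1.046 ± 0.005 and 1.039 ± 0.026 (SD, n = 3 each; exact permutation p = 0.7), and that of ACTB 4.68 ± 0.69 and 4.88 ± 0.42 (SD, n = 3 each; exact permutation p = 0.6). The same ratio of the dap spike was 7.37 ± 2.65 and 5.29 ± 0.27 (SD, n = 3 each; exact permutation p = 0.1), with 10.4 on USP2 shRNA replicate 3. For the thr and phe spikes the exact permutation p was 0.8 and 0.6. USP2 shRNA replicate 3 also had the highest score on the first principal component, 67.0 against 37.4 for the next, and the lowest array weight, 0.558.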

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

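The labelling covariate and the threshold of 0.1 were chosen after the results were seen; every other setting reported here was planned, save 1 test named below. The count of genes moved with most settings, from 9 higher and 4 lower, while 0 values called over all genes or by camera changed sign. Of 109 named genes other than USP2 and 23 lists, 14 and 13 that did not pass over all genes or by camera changed sign under at least 1 setting, among them FASN, MDM2 and the interferon list near 0, and TNIP1 and ABCG1 where another probe set stood for the gene (-0.336 and 0.355). Of 2128 comparisons of these genes 77 lost and 73 gained a call, USP2 lost its call in 4 of 20, and of 502 comparisons of lists 16 lost and 7 gained one. With an estimated correlation, added after these calls were seen, none of the 7 held (adjusted p = 0.33 to 0.86 with an estimated correlation). The counts were 31 higher and 15 lower with quantile normalization, 32 and 7 with median centring, 22 and 14 with a pseudocount of 16, 24 and 15 with a floor at the 30th percentile, 44 and 23 with a filter at the 75th percentile, 25 and 14 with robust variance, 37 and 24 with array weights, 23 and 15 with the mean of all probe sets of a gene, 18 and 11 without _x_at and _s_at probe sets, 16 and 7 with the labelling covariate, and 48 and 30 at an adjusted p below 0.1. Quantile normalization and median centring moved the median log2 difference of all probe sets by 0.018 and 0.05. Limma gave 0 higher and 0 lower with no filter, where 4330 of 54613 probe sets had an unadjusted p below 0.05, and with no intensity trend, where 2513 did; USP2 stayed at a log2 difference of -1.757 in both, with an adjusted p of 0.086 and 0.387. Leaving out 1 array in turn gave 2 to 40 genes higher, 0 to 24 lower, 3 to 7 lists higher and a USP2 log2 difference from -1.907 to -1.602; the highest counts came without USP2 shRNA replicate 3. Lists higher numbered 3 with the mean of all probe sets and 3 without _x_at and _s_at probe sets, where cytokines and NF-kB genes lost their call, 2 by fry, and 0 with an estimated correlation, where 0 lists were lower too. FABP4 and SERPINE2 passed under 18 of 20 alternatives each. With the replicate block, 9 genes were higher, 4 lower and USP2 at -1.757, but only 10 of the 13 genes kept their call: CD300A, TNF and MS4A7 lost it. With the labelling covariate 11 of the 13 kept it, and CD300A (adjusted p = 0.0615) and ETS1 (adjusted p = 0.0778) lost it; MGLL lost it without _x_at and _s_at probe sets (adjusted p = 0.0672). Same-numbered arrays had deviations correlated at 0.035, 0.012 and 0.084, so little variation was shared by replicate number. These correlations cannot show whether same-numbered samples were handled together. The cause of these moves was not tested, and some settings also removed arrays or probe sets. Probe sets with a mean signal below 70.1 were not tested in the reported fit.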

Other observations

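The tests of promyelocyte markers, of interferon-stimulated genes and of array scaling, the genes named in the next paragraph and the labelling covariate were chosen after the results were seen; the other tests were planned before their result was seen. The bound on the promyelocyte test was rewritten, and the interval of the test on probe sets with no symbol was added, once their values were known.

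Several genes outside the fixed lists lay on either side of the threshold. TNIK, a kinase of Wnt and JNK signalling, passed by 1 probe set (log2 difference 0.97 ± 0.13 SE, limma adjusted p = 0.036), and the probe set that stands for it had 0.92 (adjusted p = 0.065). SERPINA1, alpha-1 antitrypsin, passed by 1 probe set at 4562 ± 183 against 6986 ± 156 (SD, n = 3 each; limma adjusted p = 0.02), and its brightest probe set had -0.41 (adjusted p = 0.25). S100A8 and S100A9, which form the calprotectin dimer of myeloid cells, had log2 differences of -0.57 ± 0.095 and -0.68 ± 0.12 (SE; limma adjusted p = 0.056 and 0.073). The myeloid transcription factor CEBPA had -0.51 ± 0.089 (SE; limma adjusted p = 0.066). NR4A3, an orphan nuclear receptor, had 0.89 ± 0.13, the gluconeogenic enzyme FBP1 0.79 ± 0.12 and the niacin-receptor relative HCAR3 0.82 ± 0.13, while the water channel AQP3 had -0.52 ± 0.077 and the succinate receptor SUCNR1 -0.66 ± 0.10. None of these last 5 passed 0.05, and all were below 0.1.

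Cell cycle genes were lower with USP2 shRNA by a median of -0.484. The deviating array, USP2 shRNA replicate 3, was argued against as the whole cause, since the median was -0.509 without it. The median was -0.532 once the dap ratio was a covariate. That 3′ to 5′ ratio was 10.4 on USP2 shRNA replicate 3 and from 5.07 to 5.86 on the other arrays. The covariate therefore largely repeats leaving that array out, and it cannot decide on unequal labelling among the others. Fewer cells with promyelocyte markers stays open: the median of that list was -0.09, with a bootstrap interval from -0.266 to 0.0352. The bootstrap resampled the genes of the list, so its interval carries no spread between arrays. The rule first written would have excluded this explanation, because the interval lies above -0.484, but it was replaced after the value was seen, as the markers' level in the other cells is unknown and a high level there could hide a small share. In 1 of the 10 splits of the 6 arrays, the real one, the median was as large (0.484, highest other 0.216). The other splits mix both groups unevenly and so carry part of the real difference, and 10 splits cannot give a share under 0.05.

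Chemokine genes were higher by a median of 0.373. The median was 0.402 without USP2 shRNA replicate 3, which argues against that array as the whole cause. It was 0.44 with the labelling covariate, which largely repeats that test, as the dap ratio stood out on the same array. Unequal labelling among the other arrays cannot be decided by it. Interferon-stimulated genes did not rise as a list: their median was 0.00166, with a bootstrap interval over genes from -0.149 to 0.0795. That interval carries no spread between arrays, and no arm without LPS shows how far those genes were induced here. The values argue against a rise of all genes that LPS can induce only as far as these genes were induced. Loss of USP2, an off-target effect of the shRNA and a difference between the derivatives that predates LPS cannot be told apart with these samples. The same holds for the cell cycle list and for the genes called over all genes.

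Ribosomal RNA control signals were lower by a mean of -0.516 on the log2 scale. Array scaling is argued against, since the hybridization controls differed by -0.14. Less nuclear and non-polyadenylated RNA was tested through probe sets with no symbol. Their median lay -0.066 from that of probe sets with 1 symbol (bootstrap interval over probe sets -0.08 to -0.054). This was in the predicted direction but short of the bound of 0.1 set beforehand, so the prediction was not met. The bound was assumed and not measured, so the test cannot decide and the explanation stays open. Such probe sets are only a stand-in for nuclear RNA, and MALAT1 and KCNQ1OT1 went with the explanation at -0.35 ± 0.18 and -1.52 ± 0.56 (SE) without passing, and the other RNA chosen for this test was not analysed here. No biological explanation was tested.

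For the counts, 1 of the 10 splits, the real one, gave as many genes (13, highest other 0), and 3 of the 10 gave as many lists (6, highest other 6). With 10 splits no share can fall under 0.05. Every other split mixes both groups unevenly. Part of the real difference then stays between its groups, and part adds to the spread within them, which works against gene calls. The counts of those splits are therefore no measure of what arises with no difference. The other splits with 6 lists set USP2 shRNA replicates 1 and 2 with control shRNA replicate 1 or 3, apart from USP2 shRNA replicate 3.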
